A study of Mus musculus with 4 samples.

How the data were processed

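Total RNA of the parietal peritoneum was extracted with the RNeasy Mini kit and labelled with biotin by in vitro transcription, per the labels' protocols, and hybridised to 4 Affymetrix mouse arrays, 1 for each combination of genotype (wild type, BNP transgenic) and treatment (chlorhexidine gluconate, vehicle). Groups were taken from the sample labels, and the groups labelled PBS are called vehicle here. The deposited values are expression signals, an intensity on a linear scale with 1 value per probe set, per the file headers. Each signal comes with a Present, Marginal or Absent call and a detection p-value, both made by the authors, per the file headers. The algorithm, its version and the scaling target are not given in the sources used here. The series' design text says that the raw scanner image files were lost, and they were not used here. The deposited series table held the same signals as the array files, with 0 values differing.

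The 2% trimmed mean signal differed between the arrays, at 86.8 (wild type, vehicle), 103 (wild type, chlorhexidine), 116 (transgenic, vehicle) and 101 (transgenic, chlorhexidine). Each array was therefore multiplied to a common trimmed mean, by 1.17, 0.984, 0.877 and 1.01 in that order, signals under 0.1 were set to 0.1, and log2 was taken. Of 45101 probe sets, 64 controls were left out. Of the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none in the table used here. Symbols were updated through Entrez gene identifiers to a RefSeq table of assembly GRCm38.p6 for 34754 probe sets. Probe sets with several symbols or none were not named. A gene took the value of its probe set with the highest mean log2 signal, which gave 18193 genes. Some genes have no probe set with a single symbol in the table used here and are not reported here.

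With 1 array per group, differences have no replicate check and their number limits the precision. A gene was called higher or lower when its log2 difference was at least 1, it was called Present on the brighter array and its signal there was at or above the 25th percentile of that array's Present probe sets. Where the dimmer array was not Present, the fold was taken against the higher of the lowest Present signal on that array and the probe set's own signal, and is a lower bound. Comparisons were chlorhexidine against vehicle in each genotype, transgenic against wild type under each treatment, and the difference of the chlorhexidine differences. The response size used genes whose mean difference over both genotypes was at least 1. This choice would favour a genotype with noisier arrays. The SD between probe sets of a gene was 0.454 in wild type and 0.294 in transgenic mice, where that over all probe sets was 0.730 and 0.466. Between the vehicle arrays it was 0.399 (0.452 over all probe sets) and between the chlorhexidine arrays 0.261 (0.359). The disagreement was thus larger in both comparisons that hold the wild-type vehicle array, so the choice may favour wild type in the share of 83.9%. An additive model (treatment and genotype, 1 residual degree of freedom) was fitted with limma 3.58.1 in R 4.3.3 on 12754 genes Present on at least 1 array, with Benjamini-Hochberg adjustment at 0.05. Its p-values rest on 4 arrays whose number of mice is not in the labels.

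Before the data were examined, 35 gene lists were fixed (pathways, cell types of the peritoneum and abdominal wall, and technical controls). A list's median log2 difference was set beside 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. Lists with fewer than 4 measured genes are given gene by gene. Named genes followed a rule fixed at the same time. It took the natriuretic genes Nppb, Npr1, Npr2 and Npr3, and the serum amyloid P gene Apcs. It took the 12 highest and 12 lowest genes by the smaller of the genotypes' differences. It took the 10 highest and 10 lowest of each genotype comparison and of the difference of differences, the latter with vehicle arrays within 0.5. Last came up to 4 genes of each list by mean change and by difference of differences, and a short set including Col1a1, Fn1, Acta2 and Msln. The genes that went in opposite directions and the genes the limma fit called were named in full after their values were seen.

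Alternatives planned before the data were examined were quantile normalization, median centring, cyclic loess, a pseudocount of 32, no filter on dim probe sets, Present calls on all 4 arrays, the mean of a gene's probe sets, no cross-hybridising probe sets, muscle genes left out with recentring, 1.5-fold and 3-fold thresholds, and a variance prior with an intensity trend. The deposited scaling, each vehicle array alone and the brighter part of the genes were added after seeing the data. The median of all genes in the wild-type chlorhexidine difference was -0.11 under quantile normalization, -0.18 after median centring, -0.24 without muscle genes and 0.25 with the deposited scaling, under which it was -0.20 in transgenic mice, 0.37 between vehicle arrays and -0.44 in the difference of differences. Between vehicle arrays it was -0.102 after median centring and -0.153 without muscle genes, and in the difference of differences 0.128 and 0.189. List medians under alternatives were therefore compared relative to the median of all genes.

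Both procedures were tested on simulated data. Applied to the chlorhexidine difference in both genotypes, the size rule recovered 91.5% of 200 genes changed by 2 on the log2 scale. It made 25 false calls among 12754 genes. These values do not give the error of calls in a single comparison. In the same simulation 50.5% of the changes were larger in wild type, with the same noise SD, 0.393, in both genotypes. That value cannot check a bias from unequal noise, so it does not bear on the share found in the arrays. The limma fit recovered 2% of genes changed by 1, 52% by 2, 98% by 4 and 100% by 6, with 3 false calls. Its simulated noise was drawn from the fit's own variance prior, whatever the signal, and held no genotype difference in response. These values therefore cannot check the fit on the real arrays, where such differences count as error. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.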

Results

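Gene expression was measured in the parietal peritoneum, the serous lining of the abdominal wall, of C57BL/6J mice. Wild-type mice were compared with mice carrying a brain natriuretic peptide (BNP) transgene driven by the serum amyloid P promoter. BNP is a hormone that acts through the cyclic GMP-forming receptor Npr1. Mice of each genotype received chlorhexidine gluconate, an antiseptic that irritates the peritoneum, or a control called vehicle here, in groups labelled PBS. The drug went into the peritoneal cavity as a 0.1% solution, with 85% PBS and 15% ethanol as solvent, at 0.01 mL per gram of body weight in 3 injections per week over 21 days. For the groups labelled PBS the labels give no ethanol content, volume or schedule. A difference in ethanol therefore cannot be told apart from chlorhexidine. Each of the 4 groups was represented by 1 Affymetrix expression array, and the labels do not say how many mice contributed to an array.

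The arrays called 50.5% (wild type, vehicle), 55.1% (wild type, chlorhexidine), 52.5% (transgenic, vehicle) and 53.5% (transgenic, chlorhexidine) of 45037 probe sets Present. Of 18193 named genes, 12754 were Present on at least 1 array. No difference below has a replicate check. Genes were called higher or lower by a rule of size, a difference of at least 1 on the log2 scale (2-fold) with a Present call on the brighter array, and these calls carry no p-value. Where the dimmer array was not called Present, the fold is given as a lower bound. The wild-type vehicle array stood apart in its control probe sets. Its mean 18S rRNA signal was 898.5, against 82.8, 107 and 117 on the other arrays, and its ratio of 3-prime to middle beta-actin signal was 5.81, against 2.23 to 2.84. The ratios of 3-prime to 5-prime signal were closer, at 1.22 against 1.07 to 1.15 for beta-actin and 0.850 against 0.807 to 0.820 for Gapdh. Probe sets of the same gene differed from each other with an SD of 0.454 on the log2 scale in the wild-type chlorhexidine difference and 0.294 in the transgenic one.

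The transcript of the transgene's hormone was not detected on any array. Nppb, which encodes BNP, was called Absent on all 4 arrays, with signals of 6.91 and 20.1 in wild type (vehicle and chlorhexidine) and 9.04 and 4.04 in transgenic peritoneum, so these values do not check the genotype labels. Apcs, which encodes serum amyloid P, was Absent on all 4 arrays too, and Npr1 was not called Present on any. Npr3, the receptor that clears natriuretic peptides, was 5.45-fold lower with chlorhexidine in wild type (signal 252 to 46.3) and 6.19-fold lower in transgenic mice (308 to 49.8). Npr2 was 1.59-fold and 1.24-fold lower. The 19 measured genes of natriuretic peptide and cyclic GMP signalling had median log2 differences of -0.26 (-0.02 with the transgenic vehicle array in place of the wild-type one) and -0.18, and 2 of them, one being Npr3, were 2-fold lower in both genotypes. The other was Prkg1, the cyclic GMP-dependent kinase, at 2.07-fold and 2.14-fold lower.

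Chlorhexidine went with a higher signal of extracellular matrix genes in both genotypes. Col1a1, the main chain of fibrillar collagen I, was 5.44-fold higher in wild type (1060 to 5769) and 4.04-fold higher in transgenic mice (1087 to 4393). Periostin (Postn) was 6.86-fold and 4.92-fold higher, fibronectin (Fn1) 4.18-fold and 2.82-fold, and the collagen crosslinking enzyme Lox 8.12-fold and 3.90-fold. Of 19 collagen genes, 16 were 2-fold higher in wild type and 6 in transgenic mice, with median log2 differences of 1.19 and 0.85. The largest mean change among them was that of Col8a1, at 8.27-fold and 6.12-fold, whereas Col3a1 was 1.83-fold and 1.76-fold higher. Among 24 matrix glycoproteins and proteoglycans, 10 were 2-fold higher in both genotypes, with medians of 1.48 and 0.99. They included Cthrc1 (log2 differences of 3.68 and 2.81) and versican, Vcan (9.46-fold and 4.70-fold). Of 25 collagen processing and matrix remodelling enzymes, 13 were 2-fold higher in both genotypes, with medians of 1.54 and 1.11. The protease inhibitor Timp1 was 8.58-fold and 4.76-fold higher, while the macrophage elastase Mmp12 was 4.84-fold and 9.01-fold lower. Each of these 3 medians lay above all of 10000 random gene lists matched on signal, in either genotype.

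Growth factor and contractile genes moved less. Tgfb1, a driver of matrix synthesis, was 2.90-fold higher with chlorhexidine in wild type and 1.41-fold in transgenic mice. The 23 genes of TGF-beta signalling had medians of 0.52 and 0.18, with 3 genes 2-fold higher in both genotypes. Snai2, a transcription factor of mesenchymal change, was 10.4-fold and 5.81-fold higher, and the secreted matrix factor Ccn2 2.64-fold and 2.26-fold. The 18 myofibroblast and smooth muscle genes had medians of 0.40 and 0.15. Acta2, smooth muscle actin, was 1.31-fold and 1.02-fold higher, and the 2 Acta2 probe sets called Present disagreed in sign in the transgenic comparison. Vegfa, an angiogenic factor, was 1.08-fold higher in wild type and 1.78-fold lower in transgenic mice.

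Inflammatory genes formed a further group with higher signal. The monocyte chemokine Ccl2 was 13.3-fold higher with chlorhexidine in wild type and 7.52-fold in transgenic mice, and Ccl12 was 8.85-fold and at least 6.37-fold higher. Of 28 monocyte and macrophage genes, 11 were 2-fold higher in both genotypes and 1 was 2-fold lower, with medians of 1.27 and 0.91. Chil3, a chitinase-like macrophage protein, was at least 18.8-fold and 19.1-fold higher, whereas the macrophage marker Adgre1 was 1.79-fold and 1.42-fold higher. The 9 genes of large peritoneal macrophages had medians of 0.74 (bootstrap interval -0.05 to 1.61) and 0.61, with 7 and 8 of them above 0. Their transcription factor Gata6 was at least 3.06-fold and 2.92-fold higher. Of 27 chemokines and inflammatory cytokines, 9 were 2-fold higher in both genotypes, with medians of 1.24 and 0.91. Of 6 measured neutrophil genes, 4 were 2-fold higher in both, with medians of 2.46 and 2.79, the former 0.82 (bootstrap interval -0.21 to 1.41) against the transgenic vehicle array. S100a8 was 9.12-fold and 9.89-fold higher. The 16 complement and acute phase genes had medians of 0.87 and 0.95, led by complement factor Cfb (4.70-fold and 3.93-fold).

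Interferon-induced genes had the highest median of the fixed lists with more than 6 measured genes in wild type, 3.10, against 1.66 in transgenic mice. Of 22 such genes, 17 were 2-fold higher in both genotypes. Ifit1 was 17.2-fold higher in wild type (37.1 to 640) and 6.75-fold in transgenic mice (71.9 to 485). Slfn4, a myeloid gene of the schlafen family, was at least 47.4-fold and 8.21-fold higher, and Oas1b at least 16.6-fold and at least 10.7-fold. The same list was higher in transgenic than in wild-type vehicle peritoneum, with a median of 0.65, and against that array the wild-type median was 2.03.

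B and plasma cell genes were lower with chlorhexidine, by more than any other fixed list. Of 11 measured genes, 8 were 2-fold lower in both genotypes, with medians of -3.92 in wild type and -2.29 in transgenic mice. Jchain, which joins secreted antibody chains, was 41.9-fold lower in wild type and 9.29-fold in transgenic mice. The kappa light chain Igk was at least 914-fold and at least 73.2-fold lower, and the B cell receptor component Cd79a at least 19.4-fold and at least 13.9-fold lower. Immunoglobulin probe sets can hybridise with related chains, so single immunoglobulin genes are uncertain. The 13 genes of antigen presentation by MHC class II had medians of -0.52 and -1.15, with H2-Ab1 1.55-fold and 3.27-fold lower. T and NK cell genes had medians of 0.07 (0.33 against the transgenic vehicle array) and -0.07, although the cytotoxic protease Gzmb was at least 11.4-fold and at least 6.67-fold higher.

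Genes of fat and of oxidative metabolism had lower medians, with few genes past the size rule in transgenic mice. Leptin (Lep), a hormone of adipocytes, was at least 6.97-fold lower with chlorhexidine in wild type and at least 117-fold lower in transgenic mice. The 23 adipocyte genes had medians of -0.94 and -0.32, and 3 of them were 2-fold lower in both genotypes. The 27 mitochondrial genes had medians of -0.83 and -0.40, where random lists of equal signal had medians of -0.39 and -0.10. Of the mitochondrial genes, 9 were 2-fold lower in wild type and 1 in transgenic mice. That 1 gene, the uncoupling protein Ucp3, was 3.35-fold and 2.14-fold lower. Skeletal muscle genes had medians of -0.51 and -0.13, which lay at the 30.3 and 42.7 percentiles of random lists of equal signal. Relative to all genes, the wild-type muscle median was -0.51 and became 0.10 under cyclic loess, and against the transgenic vehicle array it was -0.22. In contrast, the 19 genes of muscle injury and regeneration had medians of 1.70 and 1.31, with 11 genes 2-fold higher in both genotypes. Ankrd1, a stress protein of muscle, was 13.8-fold and 7.88-fold higher.

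**Figure D1:**
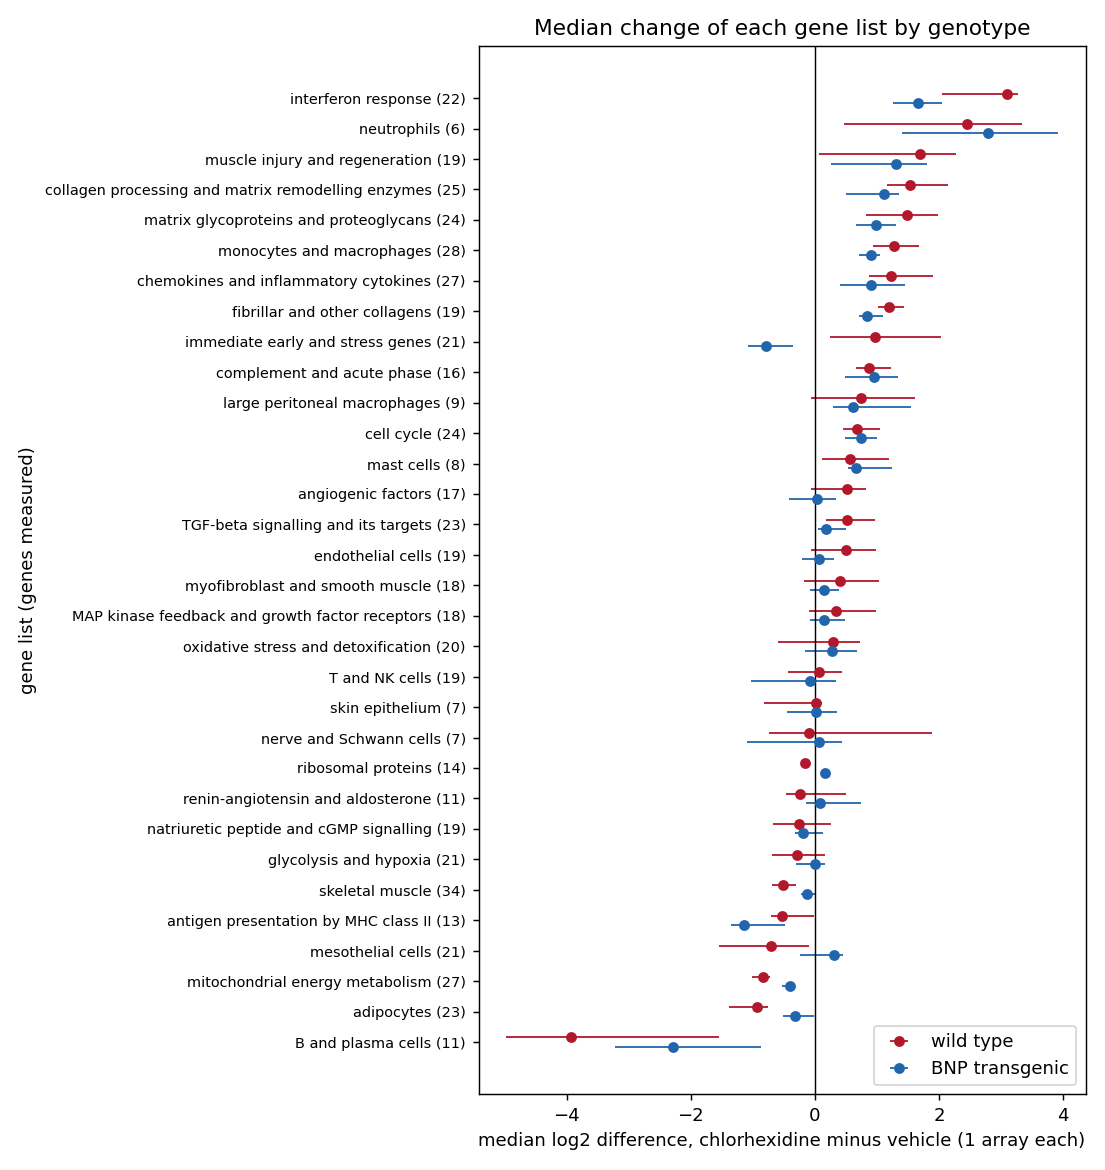
Median log2 difference between the chlorhexidine and vehicle arrays (horizontal axis) of fixed gene lists (vertical axis, number of genes in brackets). Wild type is red and BNP transgenic mice are blue. Each list with at least 4 measured genes is shown, except the sex-linked genes. Bars are 95% bootstrap intervals over the genes of a list and hold no error between mice. The interferon list lies at 3.10 and 1.66, and the B and plasma cell list at -3.92 and -2.29.

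By the rule of size, 1678 of 12754 genes differed with chlorhexidine in wild type, 1049 higher and 629 lower, and 664 in transgenic mice, 486 higher and 178 lower. In both genotypes 387 genes were higher and 105 lower, where independent lists of these sizes would share 40.0 and 8.78. Another 11 genes went in opposite directions, 8 higher and 3 lower in wild type, where independent lists would share 14.6 and 24.0. This count was 2 or 0 when both genotypes shared the transgenic or the wild-type vehicle array, which makes such calls rarer by construction. The genotypes share no array, and their chlorhexidine differences correlated across genes with Pearson's r = 0.548 and Spearman's rho = 0.588, although genes are not independent replicates. The genes highest in both by the smaller difference were Tnn (tenascin W, at least 78.8-fold and at least 25.7-fold), Chil3, Ccl3, Oas1b, S100a8, Slfn4, Ankrd1, Ccl2, Cthrc1, Ifit1, Gzmb and Ccl12. Those lowest were 8 immunoglobulin light and heavy chain genes with Jchain, Cd79a, Lep and the cilium gene Pifo. The share of higher genes depended on the scaling of the arrays. The wild-type split was 773 higher and 1073 lower after median centring, 698 and 1244 with muscle genes left out, and 1586 and 318 with the deposited scaling. The transgenic split was 329 and 320 with the deposited scaling.

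An additive limma fit over the 4 arrays (treatment and genotype, 1 residual degree of freedom) called 11 genes for chlorhexidine after Benjamini-Hochberg adjustment over all 12754 genes. By the log2 coefficient of limma at an adjusted p from 0.0343 to 0.0490 (Benjamini-Hochberg), Tnn (6.10), Slfn10-ps (4.67), Chil3 (4.24), Ccl3 (3.89), Mmp8 (3.71), Fhad1 (3.28) and S100a8 (3.25) rose. Pdcl2 (-4.46), Cd79a (-4.15), Clca3b (-3.64) and Igkv6-14 (-3.34) were the genes that decreased. Apart from S100a8, each of these genes lacked a Present call on at least 1 of its dimmer arrays, so the coefficients rest on undetected signal and do not measure the size of the change. The fit takes any difference in response between genotypes as error, and its calls for treatment ran from 0 to 2485 genes over the alternative settings at the same threshold. Adjusted over the list alone, 17 of 19 collagens passed, against 0 over all genes. The corresponding counts adjusted over the list alone were 20 of 22 for interferon genes (0 over all genes), 10 of 11 for B and plasma cells (1), 23 of 28 for monocytes and macrophages (1) and 5 of 6 for neutrophils (2).

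**Figure D2:**
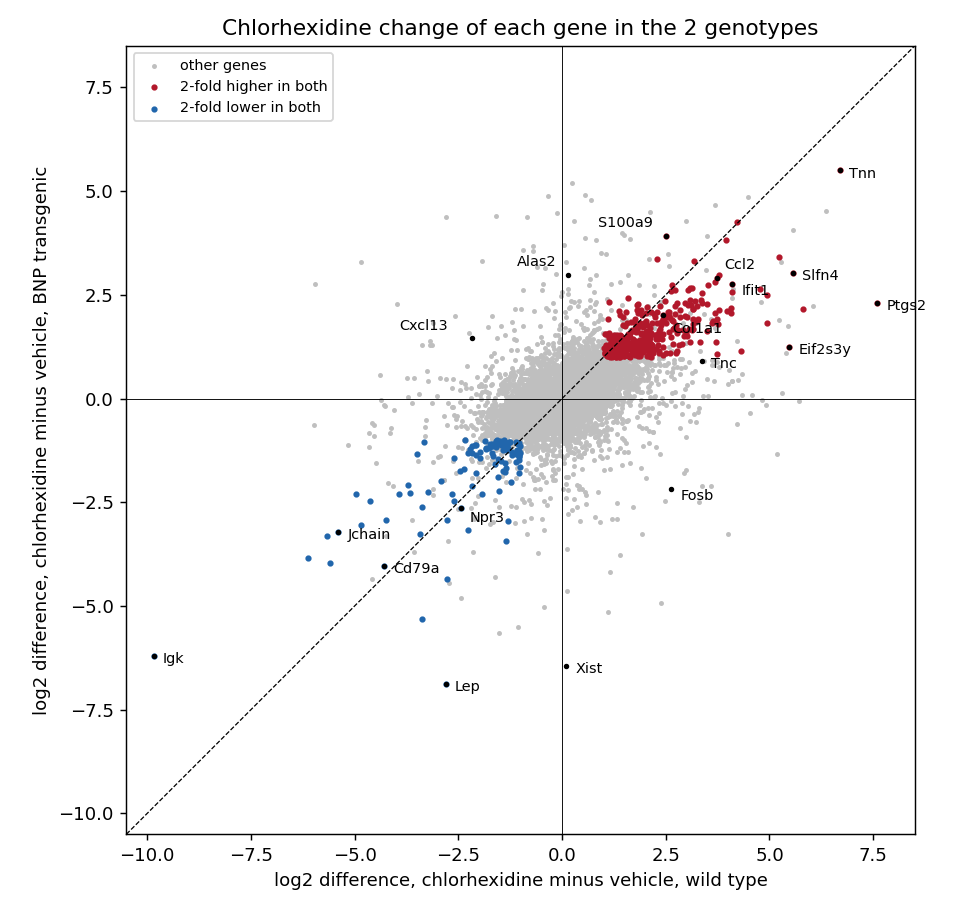
Log2 difference between chlorhexidine and vehicle for each of 12754 genes in wild type (horizontal axis) and BNP transgenic mice (vertical axis), 1 array per group. Red points are the 387 genes 2-fold higher in both and blue points the 105 genes 2-fold lower in both, black points are named genes, and the dashed line marks equal differences. Col1a1 lies at 2.44 and 2.02, and Jchain at -5.39 and -3.22.

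The chlorhexidine difference was larger in wild type for most genes that changed in size. Among 990 genes whose mean difference over the genotypes was at least 2-fold, 83.9% (Wilson 95% interval 81.5 to 86.1, counting error over genes only) had the larger difference in wild type, by a median of -0.56 for transgenic minus wild type. For the 718 higher genes the median was 1.68 in wild type and 1.16 in transgenic mice, and for the 272 lower genes -1.58 and -0.99. Tenascin C (Tnc), a matrix protein of wounds, was 10.3-fold higher in wild type (212 to 2188) and 1.89-fold in transgenic mice (300 to 565). Thrombospondin 1 (Thbs1) was 10.8-fold and 1.88-fold higher, Il6 at least 19.9-fold and 2.20-fold, and the prostaglandin synthase Ptgs2 at least 186-fold and 4.98-fold. These genes also differed between the vehicle arrays, with Thbs1 3.15-fold, Il6 at least 2.64-fold and Ptgs2 at least 8.45-fold higher in transgenic mice. The gap came from both treatments. For the higher genes the transgenic array lay below the wild-type one by a median of -0.33 under chlorhexidine and above it by 0.23 under vehicle, and for the lower genes the medians were 0.35 and -0.32. Against the transgenic vehicle array alone the share was 83.3% with a median of -0.36, against the wild-type one 78.8% with a median of -0.31, and without the filter on dim probe sets it was 63.5%.

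By the difference of the chlorhexidine differences, transgenic minus wild type, 254 genes were higher and 376 lower. The matrix lists were lower, with medians of -0.43 for collagens, -0.36 for matrix glycoproteins and -0.62 for remodelling enzymes, and so were interferon genes at -0.93. Mesothelial genes, which mark the cells lining the peritoneum, had a median of 0.70 and B and plasma cell genes 1.61. Part of these values lay between the vehicle arrays. Between the chlorhexidine arrays alone the medians were 0.04 for B and plasma cells, -0.38 for interferon genes, -0.31 for remodelling enzymes, -0.29 for matrix glycoproteins, -0.39 for collagens and 0.49 for mesothelial genes. The mesothelial list was -0.71 with chlorhexidine in wild type, with 8 of 21 genes 2-fold lower, and 0.31 in transgenic mice. Against the transgenic vehicle array the wild-type value was -0.28 (bootstrap interval -0.94 to 0.33), and the vehicle arrays themselves differed by -0.45, with 17 of 21 genes below 0. Slpi, a protease inhibitor, was lower by log2 differences of -2.56 in wild type (681 to 116) and -0.68 in transgenic mice (547 to 341), and mesothelin (Msln) was 1.63-fold lower and 1.65-fold higher. The immediate early and stress genes had medians of 0.98 in wild type and -0.78 in transgenic mice, but the wild-type value was -0.10 against the transgenic vehicle array. Among genes with like vehicle arrays, the lipogenic enzyme Fasn was 2.81-fold lower in wild type and 1.44-fold higher in transgenic mice, and the growth factor Ptn was 13.1-fold and 2.59-fold higher. No test of this difference can be made, since the fit that holds it has no residual degrees of freedom. The split was 365 higher and 287 lower under quantile normalization, 372 and 300 after median centring, 348 and 299 under cyclic loess, 473 and 267 without muscle genes, and 78 and 1297 with the deposited scaling.

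Between the chlorhexidine arrays, transgenic peritoneum had more signal of neutrophil genes and of 2 of 3 measured red cell genes. S100a9 was 11.5-fold higher in transgenic than in wild-type mice (930 against 80.5), S100a8 4.14-fold and the neutrophil collagenase Mmp8 at least 9.09-fold. The 6 neutrophil genes had a median of 1.92, with 5 of them 2-fold higher. Alas2, which makes haem in red cell precursors, was 5.54-fold higher and the red cell anion exchanger Slc4a1 5.53-fold, whereas the globin gene Hba-a2 was 1.26-fold lower. Outside that list, Car2 was 6.24-fold, Trim10 4.14-fold and Tent5c 3.93-fold higher. Adipocyte genes had a median of 0.59 and MHC class II genes -0.67, and T and NK cell genes -0.66. Lower in transgenic mice were the progesterone receptor Pgr (at least 24.6-fold), the hormone-responsive gene Greb1 (5.19-fold), the steroid enzyme gene Akr1c14 (11.6-fold), the granzymes Gzmd (at least 15.0-fold) and Gzme (at least 8.37-fold), and Ptgs2 (4.43-fold). Xist, the RNA of the inactive X chromosome, was 228-fold lower. In all, 100 genes were higher and 123 lower, a split of 130 and 105 under quantile normalization, 128 and 104 after median centring and 133 and 97 without muscle genes.

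Between the vehicle arrays, transgenic peritoneum had more signal of Y-linked, neutrophil and immediate early genes. Eif2s3y was at least 44.7-fold higher in transgenic than in wild-type mice, and Kdm5d and Uty each at least 10.2-fold, while Xist was 2.45-fold lower. Fosb was at least 14.1-fold higher, and the 21 immediate early and stress genes had a median of 0.95, with 10 of them 2-fold higher. The 6 neutrophil genes had a median of 1.42, with 2 of them 2-fold higher and S100a8 3.82-fold higher. The interferon-linked Slfn4 was at least 5.66-fold higher and the matrix protein Npnt 5.15-fold. Lower were the B cell chemokine Cxcl13 (3.23-fold), the B cell factor Pou2af1 (3.44-fold), the plasma cell protein Mzb1 (3.00-fold) and the muscle protein Ankrd2 (3.39-fold), and B and plasma cell genes had a median of -1.05. In all, 122 genes were higher and 64 lower. The split was 92 and 94 under quantile normalization, 98 and 80 after median centring, 98 and 95 under cyclic loess, 88 and 108 without muscle genes and 458 and 7 with the deposited scaling. The limma fit called 0 genes for genotype after Benjamini-Hochberg adjustment. At an unadjusted limma p under 0.05 it called 633 of 12754, a share near the 0.05 that would pass without any difference. Adjusted over the list alone, 4 of 4 sex-linked genes, 4 of 6 neutrophil genes and 1 of 7 skin epithelium genes passed for genotype (0 over all genes).

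The sex-linked genes set the arrays apart beside each of these comparisons. Xist had signals of 2276 and 2438 on the wild-type vehicle and chlorhexidine arrays, 929 on the transgenic vehicle array and 10.7 on the transgenic chlorhexidine array. Eif2s3y had signals of 3.75 (Absent), 167, 167 and 398 in that order. Kdm5d and Uty were Absent on the wild-type vehicle array and Present on the other 3. With chlorhexidine, Eif2s3y was thus higher in both genotypes and Xist lower in transgenic mice. The chlorhexidine differences therefore cannot be told apart from a difference in sex makeup either.

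**Figure D3:**
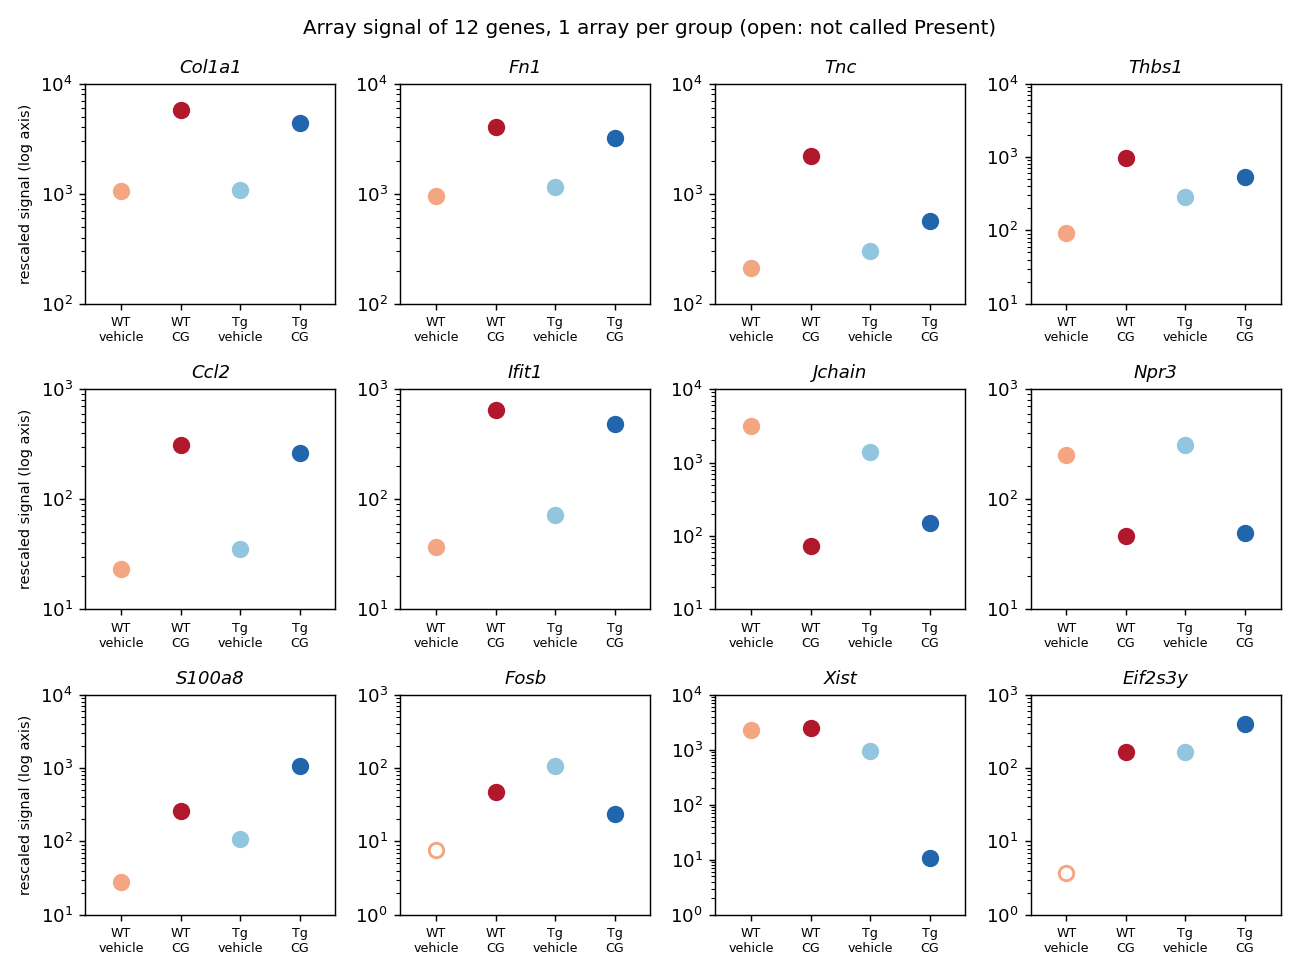
Rescaled array signal (vertical log axis) of 12 genes on the 4 arrays, wild type (WT) and BNP transgenic (Tg), with vehicle or chlorhexidine (CG). Each point is 1 array and open points were not called Present. Col1a1 runs from 1060 to 5769, and Xist lies at 10.7 on the transgenic chlorhexidine array.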

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

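The test against the transgenic vehicle array alone was written before its result was seen, and the other tests given here were chosen after the results were seen. None of the genotype differences in this part was tested against replicates.

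In 11 genes the chlorhexidine difference went in opposite directions in the genotypes. That is fewer than independent lists would share, at 8 against 14.6 (higher in wild type) and 3 against 24.0 (lower in wild type). With a single vehicle array for both genotypes the count was 2 (transgenic) or 0 (wild type), but a shared array makes opposite directions rarer by construction. The transgenic minus wild-type difference was -4.81 for Fosb, whose wild-type vehicle signal was Absent so that this value is uncertain, -3.68 for Egr2, -3.17 for Egr3, -2.63 for Fos, -2.60 for Btg2 and -2.12 for Atf3, which are immediate early genes, and -3.57 for G530011O06Rik and -2.48 for Neto2. It was 3.65 for the chemokine Cxcl13, 3.03 for Ankrd2 and 2.40 for Sox12. Over the 21 immediate early and stress genes its median was -1.38. Among control probe sets, which the comparisons leave out, the mean 18S rRNA signal of the wild-type vehicle array was 898.5. Among the 4595 Present probe sets with several or no gene symbols, 81 were 2-fold higher with chlorhexidine in both genotypes, 28 lower and 1 opposite.

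The larger chlorhexidine difference in wild type was weighed against several technical explanations. The wild-type vehicle array stands apart. With both chlorhexidine arrays set against the transgenic vehicle array, the median gap shrank from -0.56 to -0.36. The share of genes with the larger change in wild type was then 83.3%. The shared vehicle array cancels from this gap, which is then the difference between the chlorhexidine arrays. It enters only the choice of genes by mean change. There the mismatch of genotype falls on the wild-type side and can favour wild type. Against the wild-type vehicle array, where the mismatch falls on the transgenic side, the share was 78.8%. In that setting the wild-type vehicle array too enters only the choice of genes. Both shares thus describe the difference between the chlorhexidine arrays. The part of the wild-type vehicle array in the gap of -0.56 stays open. Over 5 scalings and both directions the lowest share was 61.8%, so its direction did not depend on the scaling. However, the choice of genes by mean change may favour the noisier wild-type comparison. A share in favour of wild type can therefore arise without a larger response, and this was not tested. A different share of skeletal muscle alone would move the other tissue lists alike, and the mesothelial and collagen medians lay 1.13 apart on the log2 scale. These lists were chosen after their medians were seen, and between the vehicle arrays they already stood at -0.45 and 0.04. The gap therefore cannot exclude a muscle share acting beside other differences. The sex makeup of the arrays cannot be told apart from genotype or from treatment, because 0 arrays allow a comparison within a sex and genotype. An effect of the BNP transgene was not tested and stays open.

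Xist at a signal of 100 or more was Present together with the Y-linked genes Eif2s3y, Kdm5d and Uty on 2 arrays, wild type with chlorhexidine and transgenic with vehicle. On the transgenic chlorhexidine array all 4 genes were Present too, with Xist at 10.7. A candidate explanation is RNA of both sexes pooled on the array, but the 2 arrays are the observation that raised it and do not test it. It stays open, since the labels give neither sex nor the number of mice. No biological explanation was tested.

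The immediate early genes may reflect tissue handling. Between the vehicle arrays, 13 immediate early genes were higher in transgenic tissue by a median of 1.40, and 5 heat shock genes, which also respond to handling stress, by 1.18. Elsewhere the groups lay further apart, at 2.03 and 0.32 with chlorhexidine in wild type and -0.95 and -0.11 between the chlorhexidine arrays, though at -0.94 and -1.15 with chlorhexidine in transgenic mice. The heat shock genes belong to the list that raised the question, so slower tissue handling stays open. A difference between genotypes was not tested and stays open too.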

How the results depend on the processing

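The deposited scaling, each vehicle array used alone and the brighter part of the genes were settings chosen after seeing the data, and the other settings were planned. No paired analysis was possible because the labels give no replicate numbers and each group is 1 array. The series table gave no values of its own, because it equals the array files at every probe set. Dim genes limit what the arrays show, since signals without a Present call give only bounds. Relative to all genes, 1591 of 1658 list medians under alternatives stayed within the list's bootstrap interval, 63 moved outside it, and 4 turned sign in lists outside the central 95% of random lists. Counting lists inside that central 95% as well, 79 medians turned sign, 37 of them under another scaling. Some of these were not near 0, such as the wild-type skeletal muscle median, which went from -0.51 to 0.10 under cyclic loess. Of 3670 values of named genes, 3192 kept their sign and moved by less than the SD between probe sets of a gene, 473 moved further and 5 reversed. For the values below the cause was not tested, unless the setting itself changes how many genes can pass.

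Counts of genes are given in the order wild type, transgenic, genotype under chlorhexidine, genotype under vehicle, difference of differences and both genotypes, against 1678, 664, 223, 186, 630 and 492. A pseudocount of 32 gave 950, 334, 84, 51, 221 and 257. Without the filter on dim probe sets they were 4901, 3703, 3167, 3160, 4711 and 1437, the last beside 678 opposite. A 1.5-fold threshold gave 4012, 1929, 990, 908, 2272 and 1407, and a 3-fold threshold 571, 203, 51, 35, 179 and 151. The deposited scaling gave 465 for genotype under vehicle and 1375 for the difference of differences. The wild-type vehicle array alone gave 787 genes in both genotypes, where the shared array adds to the overlap.

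The share of genes with the larger change in wild type, 83.9%, was 80.31% under quantile normalization, 80.87% under cyclic loess, 88.62% with the pseudocount, 63.47% without the filter, 80.74% without muscle genes, 86.72% with the deposited scaling, 78.81% against the wild-type vehicle array alone and 89.37% in the brighter part of the genes.

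The limma fit with Benjamini-Hochberg adjustment called 11 genes for treatment. It called 0 under quantile normalization, 0 under cyclic loess, 0 without the filter and 0 without cross-hybridising probe sets, 7 after median centring, 62 without muscle genes, 722 with the deposited scaling, 2228 with genes Present on all 4 arrays, 2358 with the pseudocount and 2485 with an intensity trend. At an adjusted threshold of 0.10 it called 738 and at an unadjusted one of 0.05 2939. For genotype it called 0, against 55 with the trend, 16 with the pseudocount, 36 with genes Present on all arrays, 51 with the deposited scaling and 633 unadjusted. The last is near the share of 0.05 of 12754 genes that would pass without any difference.

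Relative to all genes, the skeletal muscle median between vehicle arrays, -0.26, became 0.058 under quantile normalization and 0.018 under cyclic loess. Against the transgenic vehicle array the wild-type median of immediate early genes, 0.98, became -0.13 and that of oxidative stress genes, 0.30, became -0.078. With the mean of a gene's probe sets, the difference of differences of Chrng, -3.12, became 0.077 and the wild-type value of Tpm3, -1.69, became 0.17. Without cross-hybridising probe sets, the difference of differences of Igkv9-120, 1.33, became -0.53, and Trem2, 3.34 in wild type and 2.38 in transgenic mice, became -2.12 and -0.28.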

Other observations

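Other gene groups are given here as values, with no test chosen after the result was seen, apart from the setting with the transgenic vehicle array in place of the wild-type one. Cell cycle genes had median log2 differences with chlorhexidine of 0.67 in wild type and 0.74 in transgenic mice over 24 genes, and 1.25 for the wild-type chlorhexidine array against the transgenic vehicle array. Of these genes 5 were 2-fold higher in wild type, 8 in transgenic mice and 4 in both. Cdk1, the kinase of mitotic entry, was 2.61-fold and 4.06-fold higher, and the spindle protein gene Prc1 3.29-fold and 3.07-fold. The 8 mast cell genes had medians of 0.56 and 0.66, with the protease Mcpt4 2.30-fold and 2.38-fold higher. The 19 endothelial genes had medians of 0.51 (0.19 against the transgenic vehicle array) and 0.07, and the endothelial gene Plvap was 2.88-fold and 1.85-fold higher. The 17 angiogenic factors had medians of 0.52 and 0.04, and the VEGF receptor gene Kdr was 2.67-fold higher in wild type and 1.25-fold lower in transgenic mice.

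Oxidative stress and detoxification genes had medians of 0.30 (-0.05 against the transgenic vehicle array) and 0.27. Haem oxygenase Hmox1 was 5.84-fold and 1.82-fold higher, whereas the glutathione transferase Gsta4 was 3.66-fold and 1.52-fold lower. MAP kinase feedback and growth factor receptor genes had medians of 0.35 and 0.14, and renin-angiotensin and aldosterone genes -0.24 and 0.09, with Ace 2.80-fold and 2.03-fold higher. Glycolysis and hypoxia genes had medians of -0.29 and 0.00, and relative to all genes the former became 0.08 under cyclic loess. Nerve and Schwann cell genes had medians of -0.09 and 0.06 and skin epithelium genes of 0.02 and 0.02, the former becoming -0.159 under quantile normalization and -0.151 under cyclic loess relative to all genes. Ribosomal protein genes had medians of -0.16 and 0.16, and the former, relative to all genes, became 0.24 under quantile normalization and 0.41 under cyclic loess. Against the transgenic vehicle array the wild-type medians were -0.11 for glycolysis and hypoxia, -0.05 for nerve, -0.18 for skin epithelium and 0.22 for ribosomal protein genes.

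Lists with few measured genes are given by gene. Of the red cell genes, Alas2 was 1.10-fold higher with chlorhexidine in wild type and 7.85-fold in transgenic mice, Slc4a1 1.22-fold and 19.5-fold, and Hba-a2 at least 2.36-fold and at least 1.34-fold. Of the liver secreted genes, Alb was at least 3.21-fold lower in wild type and not called Present on either transgenic array, and Apoh was at least 1.28-fold lower in wild type.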
